A study of Glycine max with 12 samples.

How the data were processed

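RNA of soybean leaves was measured on 12 microarrays of Agilent with 60-base probes, each hybridised with non-inoculated leaves in Cy3 and leaves inoculated with *Xanthomonas axonopodis* pv. glycines strain 8ra in Cy5. Per the labels, the second trifoliate leaves were sprayed in a greenhouse and the RNA was labelled with the Low RNA Input Linear Amplification Kit PLUS. The 4 groups of 3 arrays were resistant and susceptible leaves at day 1 and day 10. Every array had the same dye orientation, so a dye effect of a probe remains in the 4 single responses. In differences between groups it cancels only where it is the same in the groups compared.

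Per the file headers, the spots were extracted with Agilent Feature Extraction 9.5.3.1, and the deposited mean signals, backgrounds and processed signals are intensity values in scanner units. The scanner's log ratios are log10 values per the file headers. The authors' value table holds log2 ratios of Cy5 over Cy3, read as such because each column correlated with the scanner's log ratio at 0.991 to 0.999 across probes with a slope near 1, and the authors' method is not stated. The other deposited columns are flags for saturation, outlying spots and signal well above background.

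Mean signals were background corrected with normexp (offset 50) and each array was normalised by loess (span 0.3) with limma 3.58.1 in R 4.3.3, and the files were read with the package data.table (version 1.17.8). Control spots and spots with an outlier flag had no weight in the loess, and outlier spots (14 to 124 per array) were set to missing. A probe was tested where it was well above background in at least 1 channel on at least 3 arrays, which kept 37958 of 39208 probes; a probe with missing values in a comparison was not tested there. Medians of net signal and the share of probes above background are given per channel in the report, and the number of arrays limits the precision.

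For each probe limma fitted the 4 group means, with 8 residual degrees of freedom where no spot was missing and fewer otherwise. Moderated statistics with Benjamini-Hochberg adjustment were used at 0.05 in each of 10 comparisons. These were the 4 responses, resistant minus susceptible at each day, and day 10 minus day 1 in resistant and in susceptible leaves. The others were the interaction of resistance and day, and resistant against susceptible leaves in Cy3. The last used signals normalised by quantiles of the average intensity and averaged over both arrays of a line. A number was taken as the same source in both titles of a line, so fits with line as a block are given beside the changes between days, the interaction and the Cy3 comparison. The deviations of a line's ratios from its group mean correlated between the days at 0.0133 to 0.603 across probes, which are not independent replicates, and were lowest for S50.

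Comparisons, the rule for naming probes and the alternatives were set before the data were examined, except slide as a fixed block for the interaction and the Cy3 comparison and the removal of saturated probes, which were added later. The rule took called probes with 1 sign on all 3 arrays of a group, or with no overlap between the groups. Of each entry it kept the passing probe with the highest mean signal. It then took the 8 largest in each direction, of which 2 per direction are printed and all 4 of the interaction. The 4495 GenBank entries have 2 probes each, and the other probe of a named entry is not given. Where either probe of an entry was called, both were called in 40 of 93 entries for the difference at day 1. At day 10 both were called in 85 of 170. The rule's condition that a probe have a gene name was dropped. Of 34713 entries, 0 matched the gene table supplied and 0 had a description. For that reason 0 of 27 gene lists could be tested.

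Alternatives were the scanner's log ratios, median centring, scale normalisation between arrays, no filter and a stricter filter, the arrays of the compared groups alone, line and slide as blocks, array weights, the authors' table, single days, quantile normalisation of Cy3 alone and the scanner's processed Cy3 signal for the Cy3 comparison, and each array left out. Slide was read per the file headers: R46, R47, R49 and S50 shared 1 slide on each day and S51 and S52 another. Slide as a fixed block therefore leaves S50 as the only susceptible array compared with resistant ones.

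The fits were tested on simulated data of 37958 probes with 100 probes changed 2-fold and 100 changed 4-fold. In a single response 42 and 97 of them were recovered with 5 false calls, in a difference between groups at day 1 12 and 65 with 3, in the change between days 15 and 75 with 4, in the interaction 0 and 36 with 2, and in the Cy3 comparison 36 and 85 with 2. The simulated noise was independent and normal, with the fitted spread of a probe equal in all groups and no correlation by line or slide. These counts do not measure the errors where the real arrays depart from those settings. The inoculated channel of all 12 arrays lay on the side of its label over 70 probes that separate resistant from susceptible lines.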

Results

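Soybean leaves were sprayed with *Xanthomonas axonopodis* pv. glycines, the bacterium that causes bacterial pustule, and the RNA of inoculated leaves was set against the RNA of non-inoculated leaves of the same source on 12 microarrays with both dyes. The plants were near-isogenic lines, which share most of their genome and were selected here for their reaction to the disease. Numbers R46, R47 and R49 carried resistant leaves and numbers S50, S51 and S52 susceptible leaves, and each number was hybridised once for day 1 and once for day 10 after inoculation, which gave 4 groups of 3 arrays. The labels do not say whether a number marks a line, a plant or a pool of plants, so the p-values measure the spread between these numbered samples; they are called lines here. On every array the non-inoculated leaves were labelled with Cy3 and the inoculated leaves with Cy5, and a ratio above 0 on the log2 scale means more RNA after inoculation. The question of the design was how resistant and susceptible plants differ in expression over time after inoculation, and the samples analysed here cover day 1 and day 10. The files give each probe a GenBank or UniGene entry with its sequence but no gene name or position, so probes are named by entry.

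Between 88.3% and 96.7% of the 39208 non-control probes were well above background in a channel. The median net intensity ranged from 3446 to 6500 in Cy3 and from 3957 to 6455 in Cy5. Between 989 and 4180 probes of a channel were saturated. The values of Gma#S4897034, CS416144.1, Gma#S4943143, Gma#S21540622, Gma#S45571233, Gma#S45533208, Gma#S45540140 and, at day 10, AX392312.1 include a saturated spot on 1 array of a group and are approximate for that reason. Spots that carried 1 probe sequence in more than 1 place differed by a median of 0.04 to 0.07 on the log2 scale within an array (1455 pairs), well below the differences reported here, so the 3 arrays per group, not the spots, limited the precision. The ratios of the 3 resistant arrays of day 1 correlated with each other at r = 0.63 to 0.68 across probes, those of resistant day 10 at 0.63 to 0.77 and those of susceptible day 10 at 0.70 to 0.78. Among the susceptible arrays of day 1, S50 and S52 correlated at 0.78, while S51 correlated with S50 at 0.23 and with S52 at 0.12. Genes are not independent replicates, so these coefficients describe the arrays only.

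**Figure D1:**
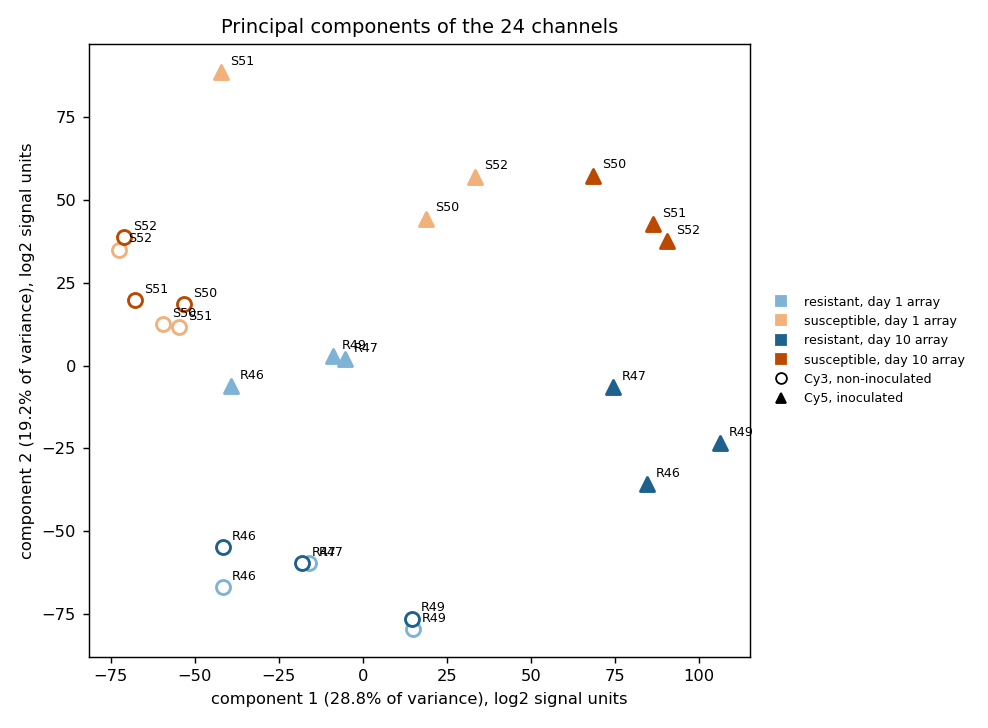
Principal components of the log2 signals of the 24 channels (component 1, 28.8% of the variance, and component 2, 19.2%, in log2 signal units); open circles are Cy3 (non-inoculated) and filled triangles Cy5 (inoculated), coloured by the group of the array and marked with the line. The Cy5 channels of day 10 lie at the right, the Cy3 channels of a line lie close together whichever day their array belonged to, and the Cy5 channel of S51 on day 1 lies at the top left, apart from S50 and S52.

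In resistant leaves at day 1, inoculation raised 3433 probes and lowered 3114 of 37957 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 1322 of the raised and 1202 of the lowered ones changed at least 2-fold. Among probes that moved the same way on all 3 arrays, 1 per entry, the largest rise was in GenBank entry CS560318.1 (probe sequence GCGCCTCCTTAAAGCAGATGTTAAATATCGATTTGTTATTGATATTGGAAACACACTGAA). Its log2 ratio was 4.40 ± 0.36 (SD, n = 3, a 21.1-fold rise, limma adjusted p = 0.00194). Next was UniGene entry Gma#S5145768 (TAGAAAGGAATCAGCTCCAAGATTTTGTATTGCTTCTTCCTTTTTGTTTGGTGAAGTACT), at 4.36 ± 0.27 (SD, n = 3; limma adjusted p = 0.000464). The largest falls were in CS137798.1 (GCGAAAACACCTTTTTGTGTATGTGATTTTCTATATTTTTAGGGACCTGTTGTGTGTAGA), at -3.44 ± 0.38 (SD, n = 3; limma adjusted p = 0.00922), and in Gma#S4897034 (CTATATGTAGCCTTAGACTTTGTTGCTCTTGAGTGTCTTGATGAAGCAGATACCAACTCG), at -3.41 ± 0.17 (SD, n = 3; limma adjusted p = 0.00190). Without R46, R47 or R49 the count of 6547 came to 3787, 3037 and 1791, and without R49 the fall of CS137798.1 no longer passed (limma adjusted p = 0.0696). All 3 arrays lay on 1 slide with S50, whose ratios correlated with theirs at 0.25 to 0.46 across probes.

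In susceptible leaves at day 1, inoculation raised 2969 probes and lowered 2699 of 37957, and 1129 of the raised and 1014 of the lowered ones changed at least 2-fold. By the same rule, the largest rises were in Gma#S45557285 (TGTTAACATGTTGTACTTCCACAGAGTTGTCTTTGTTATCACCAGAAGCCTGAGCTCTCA), with a log2 ratio of 4.91 ± 0.31 (SD, n = 3; a 30.1-fold rise, limma adjusted p = 0.00145), and in Gma#S39301538 (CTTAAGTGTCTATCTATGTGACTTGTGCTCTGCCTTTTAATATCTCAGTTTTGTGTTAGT), at 4.74 ± 0.51 (SD, n = 3; limma adjusted p = 0.000596). The largest falls were in Gma#S39306354 (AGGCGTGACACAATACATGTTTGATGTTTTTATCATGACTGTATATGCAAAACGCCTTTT), at -2.88 ± 0.95 (SD, n = 3; limma adjusted p = 0.00163), and in Gma#S4885488 (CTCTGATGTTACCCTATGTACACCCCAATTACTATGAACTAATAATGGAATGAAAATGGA), at -2.58 ± 0.49 (SD, n = 3; limma adjusted p = 0.000409). Of the called probes, 80 rose at least 8-fold and 0 fell at least 8-fold. Without S50 or S52 the count of 5668 came to 1977 and 1753, without S51 to 8263, and with the spread of this group alone to 95 (93 higher and 2 lower), where Gma#S39306354 and Gma#S4885488 no longer passed (limma adjusted p = 0.102 and 0.0791).

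In resistant leaves at day 10, 4520 probes rose and 4351 fell of 37956, and 1846 of the raised and 1699 of the lowered ones changed at least 2-fold. Gma#S23069122 (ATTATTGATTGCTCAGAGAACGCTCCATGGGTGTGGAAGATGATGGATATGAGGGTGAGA) rose at least 17.9-fold, a bound because its Cy5 spot was saturated on all 3 arrays (limma adjusted p = 0.00771). DD098007.1 (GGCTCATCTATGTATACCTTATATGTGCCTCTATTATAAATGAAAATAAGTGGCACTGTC) had a log2 ratio of 4.13 ± 0.25 (SD, n = 3; limma adjusted p = 0.00157). Gma#S4921259 (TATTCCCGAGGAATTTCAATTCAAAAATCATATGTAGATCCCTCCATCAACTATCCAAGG) fell to -3.89 ± 0.34 (SD, n = 3; limma adjusted p = 3.22e-05) and Gma#S4873105 (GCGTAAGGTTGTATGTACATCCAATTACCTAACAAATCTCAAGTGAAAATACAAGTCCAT) to -3.79 ± 0.36 (SD, n = 3; limma adjusted p = 0.000162). Without R46, R47 or R49 the count of 8871 came to 5248, 4612 and 5103, and without R49 the rise of Gma#S23069122 no longer passed (limma adjusted p = 0.0516).

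Susceptible leaves at day 10 had the most calls of the 4 groups, 6486 probes raised and 6075 lowered of 37958, or 33.1% of those tested. At least 2-fold changes were seen in 2835 of the raised and 2750 of the lowered probes, and 248 probes rose at least 8-fold. Gma#S21537554 (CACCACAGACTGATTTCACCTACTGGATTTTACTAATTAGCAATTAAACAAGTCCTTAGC) had a log2 ratio of 5.29 ± 0.015 (SD, n = 3; limma adjusted p = 3.32e-05), a rise of at least 39.1-fold because Cy5 was saturated on 2 of the 3 arrays, which may also narrow the SD. AX463283.1 (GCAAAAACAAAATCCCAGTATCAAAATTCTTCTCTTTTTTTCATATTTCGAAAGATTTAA) followed at 4.99 ± 0.34 (SD, n = 3; limma adjusted p = 1.27e-05). The largest falls were in Gma#S5128087 (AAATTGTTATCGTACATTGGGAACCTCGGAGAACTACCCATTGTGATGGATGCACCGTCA), at -4.09 ± 0.24 (SD, n = 3; limma adjusted p = 0.000303), and in Gma#S4921259, at -3.96 ± 0.23 (SD, n = 3; limma adjusted p = 9.58e-06), the entry that also fell in resistant leaves at day 10. Without S51 or S52 the count of 12561 came to 7723 and 7509.

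**Figure D2:**
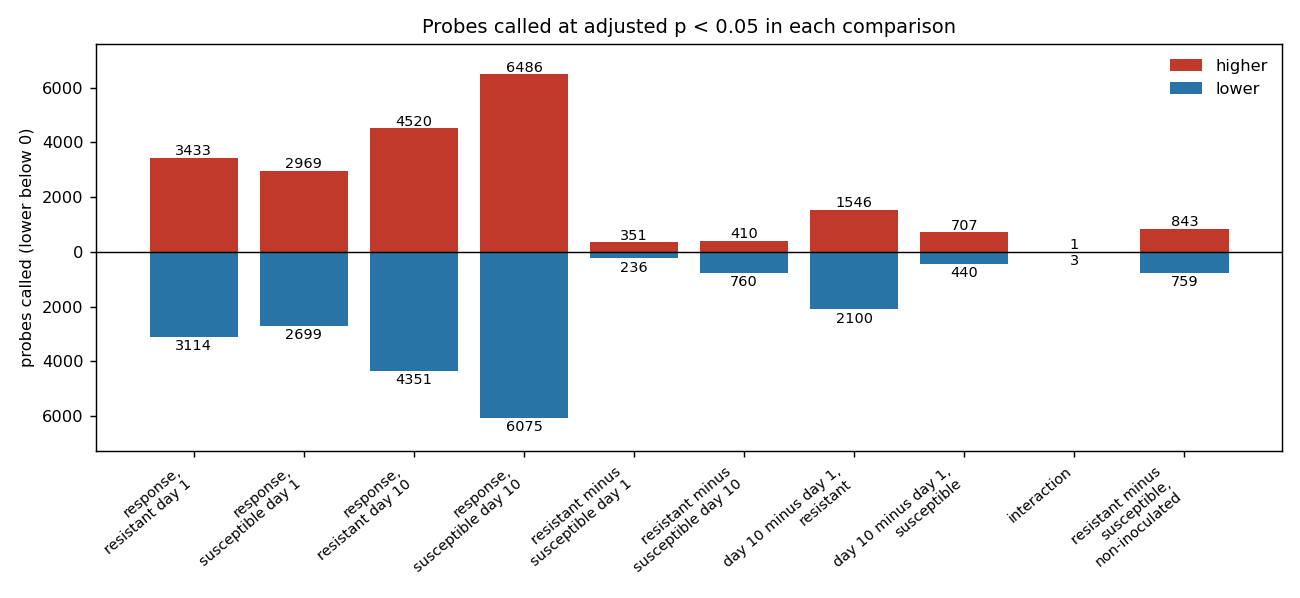
Number of probes called at a limma adjusted p under 0.05 in each of the 10 comparisons, with probes higher above 0 and probes lower below 0. The susceptible day 10 response has the most calls (6486 higher, 6075 lower) and the interaction the fewest (1 higher, 3 lower).

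The 4 single responses share 1 dye orientation, so a dye preference of a probe or transcript stays in them. Where it is the same in the groups compared, it cancels in the differences that follow. At day 1, 1162 probes rose and 1103 fell in both resistant and susceptible leaves, where independent lists would share 269 and 221, and 85 were called in opposite directions against 488 by independence. At day 10, 2655 rose and 2557 fell in both (772 and 696 by independence), and 124 went in opposite directions. Across probes the mean ratios of resistant and susceptible leaves correlated at r = 0.48 on day 1 and 0.65 on day 10. A total of 967 probes were called in the same direction in all 4 groups, 558 higher and 409 lower.

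**Figure D3:**
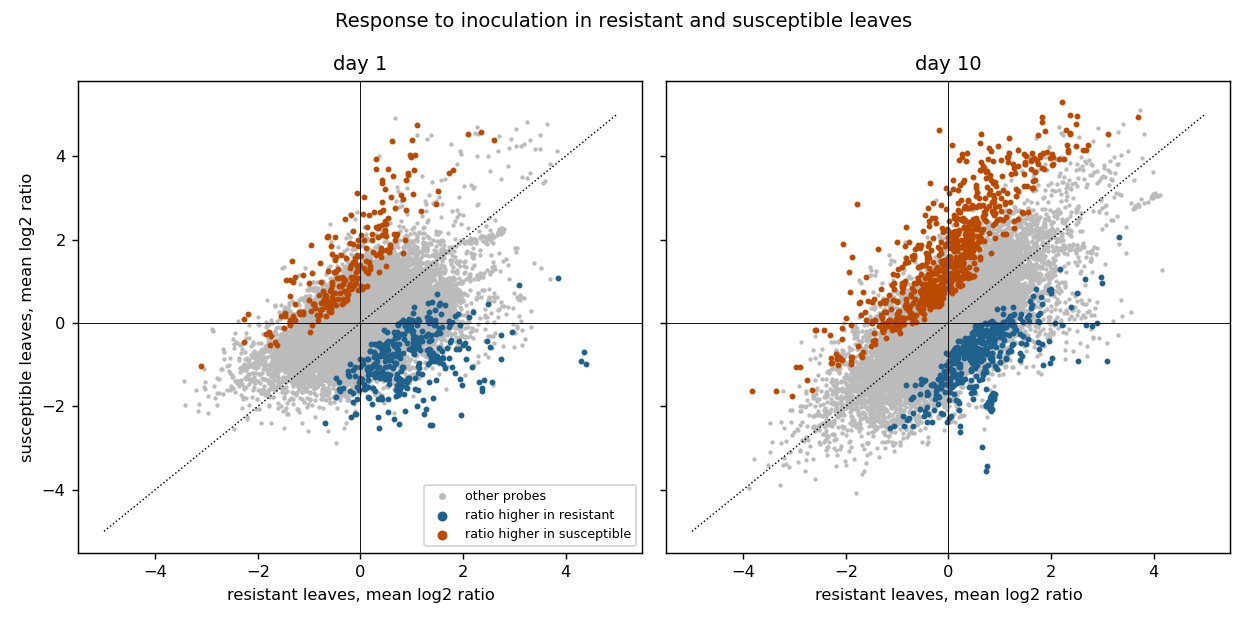
Mean log2 ratio of inoculated over non-inoculated leaves for each tested probe, resistant leaves on the horizontal axis and susceptible leaves on the vertical axis, at day 1 and day 10. Coloured points are the 587 (day 1) and 1170 (day 10) probes whose response differed at a limma adjusted p under 0.05, and the dotted line marks equal ratios.

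At day 1 the response differed between resistant and susceptible leaves in 587 of 37957 probes, with the ratio higher in resistant leaves in 351 and lower in 236. CS560318.1 stood highest: its ratio was 4.40 ± 0.36 in resistant and -0.99 ± 1.36 in susceptible leaves (SD, n = 3 each), a difference of 5.39 with a standard error of 0.85 (limma adjusted p = 0.0215). Gma#S5145768 was alike, at 4.36 ± 0.27 against -0.69 ± 1.32 (limma adjusted p = 0.00813). In the other direction Gma#S21537554 had ratios of 0.62 ± 1.20 in resistant and 4.36 ± 0.15 in susceptible leaves (limma adjusted p = 0.0236), and Gma#S39301538 of 1.10 ± 1.44 and 4.74 ± 0.51 (limma adjusted p = 0.0442). In resistant leaves Gma#S21537554 was well above background on 2 of 3 arrays in Cy3 and on 1 of 3 in Cy5, and Gma#S39301538 on 2 of 3 in Cy3, so these resistant ratios and the differences from them are not exact. Of the 587 probes, 143 rose in resistant leaves and were not called in susceptible ones, 137 fell in susceptible leaves and were not called in resistant ones, 133 rose in susceptible leaves alone by the same rule, 65 rose in resistant and fell in susceptible leaves, and 20 did the reverse. The count rested on single arrays: it was 25, 263 or 15 without R46, R47 or R49, 40 or 26 without S50 or S52, and 3079, with all 587 among them, without S51. The call of CS560318.1 ended without R46, R47, R49, S50 or S52 (limma adjusted p = 0.0535 to 0.0911), that of Gma#S5145768 without R49 (0.0556), and those of Gma#S21537554 and Gma#S39301538 without R46, R49, S50 or S52 (0.0780 to 0.162). With slide as a block, which leaves S50 as the only susceptible array on a slide with resistant ones, limma called 0 probes (3476 at an unadjusted p under 0.05). The count was 71 (58 higher and 13 lower) with the compared groups alone, where the 4 named calls ended (limma adjusted p = 0.0556 to 0.108), 1235 with scale normalisation and 3394 with array weights.

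At day 10 the response differed in 1170 of 37956 probes, and here most, 760, had the higher ratio in susceptible leaves against 410 in resistant leaves. CS416144.1 (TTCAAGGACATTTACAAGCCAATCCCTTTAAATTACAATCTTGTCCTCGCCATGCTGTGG) had ratios of -0.18 ± 1.63 in resistant and 4.64 ± 0.17 in susceptible leaves (SD, n = 3 each; limma adjusted p = 0.00649). Gma#S4943143 (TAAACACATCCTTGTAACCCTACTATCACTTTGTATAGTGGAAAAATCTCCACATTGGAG) moved in opposite directions, -1.79 ± 0.038 against 2.85 ± 0.83 (limma adjusted p = 0.00492). CS560318.1 again had the higher ratio in resistant leaves, 0.75 ± 1.84 against -3.44 ± 0.37 (limma adjusted p = 0.0290), as did Gma#S39309192 (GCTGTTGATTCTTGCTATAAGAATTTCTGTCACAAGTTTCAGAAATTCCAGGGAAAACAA), 3.09 ± 0.81 against -0.91 ± 1.97 (limma adjusted p = 0.0406). Of the 1170 probes, 422 rose and 186 fell in susceptible leaves and were not called in resistant ones. In resistant leaves 132 rose and 98 fell and were not called in susceptible ones. Another 59 rose in resistant and fell in susceptible leaves, 64 did the reverse, and 209 moved in 1 direction in both by different amounts. A total of 215 probes differed on both days, 211 of them in 1 direction. Both days used the same lines, so they are not independent sets, and no value without a shared line was available. The split by direction depended on the scaling: with median centring in place of loess, 631 were higher in resistant leaves and 546 lower. The count was 545 or 416 without R47 or R49, 749, 435 or 640 without S50, S51 or S52, and limma called 0 with slide as a block (2887 at an unadjusted p under 0.05). The call of CS560318.1 ended without R47, R49, S50, S51 or S52 (limma adjusted p = 0.0582 to 0.107) and that of Gma#S39309192 without any array but S52 (0.0591 to 0.140). The count was 321 with the compared groups alone, where CS560318.1, Gma#S39309192 and CS416144.1 no longer passed (limma adjusted p = 0.0569 to 0.115), 628 with scale normalisation and 3195 with array weights.

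**Figure D4:**
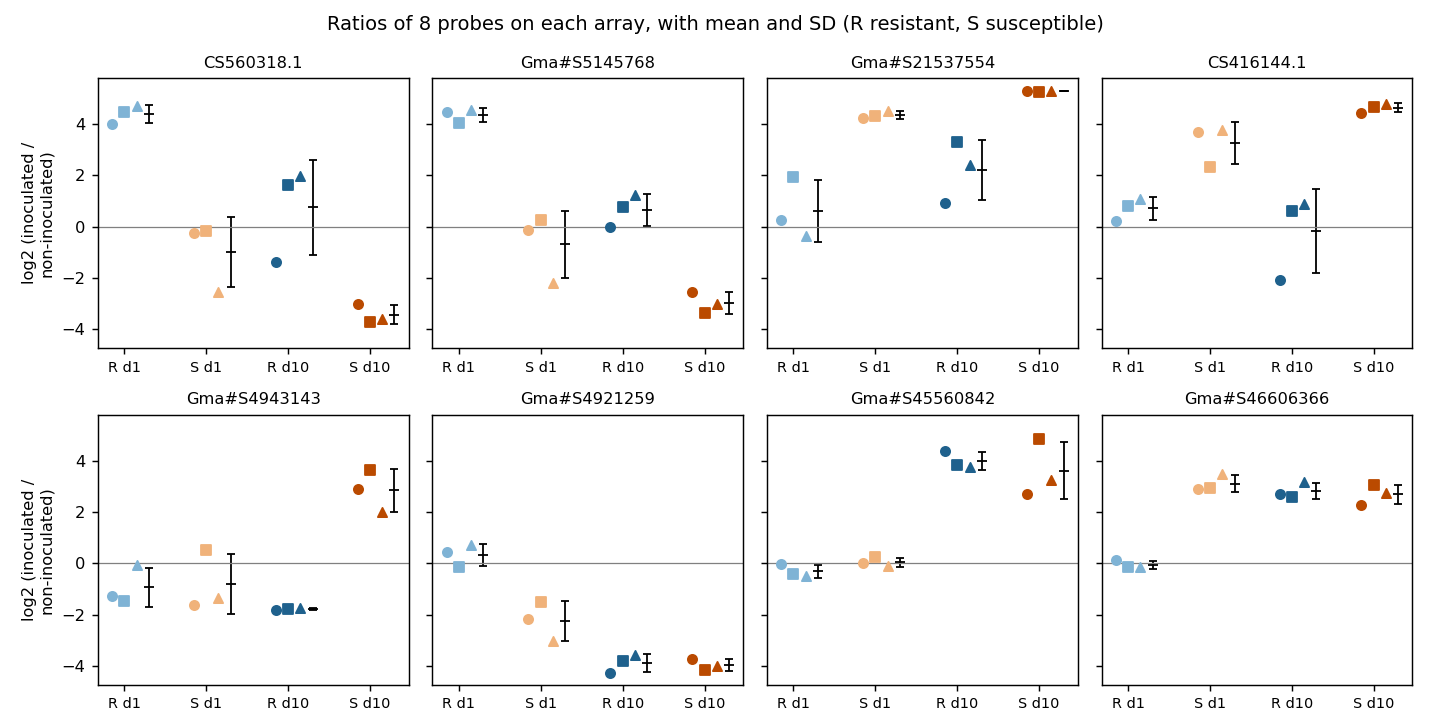
Log2 ratio of inoculated over non-inoculated leaves for 8 probes on each of the 12 arrays (circles R46 or S50, squares R47 or S51, triangles R49 or S52), with the mean and SD of the 3 arrays beside them. CS560318.1 and Gma#S5145768 rose in resistant leaves at day 1, and Gma#S46606366 was near 0 in resistant leaves at day 1 and between 2 and 4 in the other groups.

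From day 1 to day 10 the response of resistant leaves changed in 3646 of 37956 probes, 1546 upward and 2100 downward. Gma#S45560842 (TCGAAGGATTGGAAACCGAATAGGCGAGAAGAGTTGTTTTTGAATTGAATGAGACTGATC) went from -0.31 ± 0.25 to 3.99 ± 0.34 (SD, n = 3 each; limma adjusted p = 0.00170) and Gma#S21540622 (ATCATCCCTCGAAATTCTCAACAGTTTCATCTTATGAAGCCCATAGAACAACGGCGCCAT) from -0.51 ± 0.36 to 3.32 ± 0.27 (limma adjusted p = 0.0117). Gma#S45571233 (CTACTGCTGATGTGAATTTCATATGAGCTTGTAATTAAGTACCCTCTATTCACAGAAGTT) turned from 2.68 ± 1.49 to -3.07 ± 0.98 (limma adjusted p = 0.00616). AX392312.1 (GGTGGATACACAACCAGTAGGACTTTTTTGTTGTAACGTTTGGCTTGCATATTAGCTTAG) turned from 3.13 ± 1.55, a lower bound since Cy5 was saturated on all 3 arrays of day 1, to -2.32 ± 1.31 (limma adjusted p = 0.0123). With line as a block, which pairs the days of a line, the count was 5543. It was 2045 or 981 without the day 1 arrays of R47 or R49 and 1436 or 1997 without the day 10 arrays of R46 or R47; without the day 1 array of R49, Gma#S21540622 and AX392312.1 no longer passed (limma adjusted p = 0.0544 and 0.0579). The resistant arrays of each day lay on 1 slide, so they alone do not separate day from slide.

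In susceptible leaves the response changed between the days in 1147 of 37957 probes, 707 upward and 440 downward. Gma#S42153809 (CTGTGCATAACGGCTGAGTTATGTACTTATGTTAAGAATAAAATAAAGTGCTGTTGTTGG) went from -1.03 ± 0.69 to 3.89 ± 1.14 (SD, n = 3 each; limma adjusted p = 0.00518) and DJ381531.1 (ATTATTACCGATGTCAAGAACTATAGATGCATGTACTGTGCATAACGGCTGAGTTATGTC) from -1.01 ± 0.66 to 3.51 ± 0.77 (limma adjusted p = 0.00351). Gma#S45552984 (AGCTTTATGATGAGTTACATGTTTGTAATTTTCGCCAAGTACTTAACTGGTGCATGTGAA) went from 1.27 ± 1.18 to -3.34 ± 0.58 (limma adjusted p = 0.00610) and Gma#S45549946 (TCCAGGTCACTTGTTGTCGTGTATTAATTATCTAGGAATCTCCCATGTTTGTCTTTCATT) from 2.84 ± 1.28 to -1.26 ± 0.83 (limma adjusted p = 0.0499), a call at the edge of the threshold. The call of Gma#S45549946 ended under several settings, among them no filter on dim probes (limma adjusted p = 0.0511), and without the day 1 array of S50 or S52 or any day 10 array (0.0863 to 0.163). With line as a block the count was 2208, and with the spread of these groups alone it was 45 (42 higher and 3 lower) and the other 3 calls ended too (0.0572 to 0.0672). It was 150 or 625 without the day 1 arrays of S50 or S52, and 196 or 319 without the day 10 arrays of S51 or S52. The arrays of each day lay on a different pair of slides, with S50 apart from S51 and S52.

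The interaction, which asks whether the change from day 1 to day 10 differed between resistant and susceptible leaves, was called in 4 of 37956 probes. Gma#S46606366 (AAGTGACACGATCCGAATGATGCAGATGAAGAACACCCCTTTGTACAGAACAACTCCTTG) was at -0.057 ± 0.15 in resistant leaves at day 1 and at 2.81 ± 0.31 at day 10, while susceptible leaves were at 3.12 ± 0.31 on day 1 and at 2.69 ± 0.39 or more on day 10 (SD, n = 3 each; limma adjusted p = 0.0366). Its Cy5 spot was saturated on all 3 susceptible arrays and on 1 resistant array of day 10, so its interaction is not an exact value. Gma#S45563973 (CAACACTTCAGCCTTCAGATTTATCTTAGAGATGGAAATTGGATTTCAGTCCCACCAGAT) was at 0.37 ± 0.30 and -2.15 ± 0.21 in resistant leaves and at -1.32 ± 0.099 and -1.01 ± 0.43 in susceptible leaves on day 1 and day 10 (limma adjusted p = 0.0490). Gma#S45540140 (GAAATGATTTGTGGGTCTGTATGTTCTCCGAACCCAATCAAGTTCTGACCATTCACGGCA) was at 0.07 ± 0.0035 and -1.90 ± 0.17 in resistant leaves and at -1.46 ± 0.13 and -0.99 ± 0.34 in susceptible leaves (limma adjusted p = 0.0366). In these 3 probes the ratio lay away from 0 in susceptible leaves on both days and in resistant leaves at day 10. Gma#S39312610 (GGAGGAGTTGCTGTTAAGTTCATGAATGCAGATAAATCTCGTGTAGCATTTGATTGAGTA) was at 0.49 ± 0.25 and 0.42 ± 0.06 in resistant leaves and at 0.18 ± 0.23 and 2.76 ± 0.34 in susceptible leaves (limma adjusted p = 0.0366). With line as a block 66 probes passed, the 4 among them, while limma called 0 with slide as a block or with median centring (1044 and 2728 at an unadjusted p under 0.05). All 4 calls ended without any single array other than the day 10 array of S50 (limma adjusted p from 0.0601 to 0.193), and without that array the call of Gma#S39312610 ended (0.0534).

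Non-inoculated resistant and susceptible leaves also differed from each other. In the Cy3 channel, with both arrays of a line averaged, 843 probes were higher and 759 lower in resistant lines of 37957 (limma adjusted p under 0.05), and 26 were at least 8-fold higher and 44 at least 8-fold lower. Gma#S45533208 (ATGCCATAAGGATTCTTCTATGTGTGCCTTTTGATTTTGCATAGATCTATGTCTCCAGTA) had a log2 signal of 15.88 ± 0.25 in resistant and 7.64 ± 0.022 in susceptible lines (SD, n = 3 lines each; limma adjusted p = 1.92e-05), where it was well above background on 2 of 6 arrays. Gma#S5100915 (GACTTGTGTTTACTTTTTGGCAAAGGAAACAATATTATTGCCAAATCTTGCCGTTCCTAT), saturated on all 6 arrays of resistant lines, was at least 80.2-fold higher there (limma adjusted p = 0.000254). Gma#S4992150 (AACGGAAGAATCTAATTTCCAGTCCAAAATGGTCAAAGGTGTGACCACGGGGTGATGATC) was at 7.81 ± 0.067 in resistant lines, well above background on 1 of 6 arrays, and at 15.39 ± 0.54 in susceptible lines (limma adjusted p = 0.000178). Gma#S5134713 (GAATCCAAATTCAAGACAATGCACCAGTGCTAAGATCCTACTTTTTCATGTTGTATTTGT) was at 8.09 ± 0.24, well above background on 4 of 6 arrays, and at 14.99 ± 0.82 (limma adjusted p = 0.00147). CS560318.1 had 11.80 ± 1.05 in resistant and 15.15 ± 0.41 in susceptible lines, with the lower level in the lines where its ratio rose at day 1. Of the 587 probes whose response differed at day 1, 148 differed without inoculation, 137 of them in the direction opposite to their response difference. Of the 1170 at day 10, 216 differed without inoculation, 194 of them in the opposite direction. The Cy3 values enter both the response difference and this comparison, so part of that opposition is arithmetic. The baseline count was 225, 257, 163, 783 or 166 without R47, R49, S50, S51 or S52, and 36 with slide as a block. It was 5341 when the 12 arrays entered singly with line as a random block. That fit takes its residual degrees of freedom from the 12 arrays rather than the 6 lines, so its count is not on the same footing.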

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

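The splits of the samples and the test of inoculated tissue on the day 1 array of S51 over probes of resistant leaves were planned before their results were seen, and the other tests on S51, on the Cy3 channels and on the shared probes were chosen after.

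The results listed here are those in which the response differed between groups by the test of the difference itself. The groups of 3 arrays were too small for a test of single outlying arrays. The response differed between resistant and susceptible leaves in 587 probes at day 1, by 5.39 in CS560318.1, 5.05 in Gma#S5145768, -3.74 in Gma#S21537554 and -3.64 in Gma#S39301538 on the log2 scale, the last pair not exact because resistant spots lay near background. At day 10 it differed in 1170 probes, by 4.19 in CS560318.1, 4.003 in Gma#S39309192, -4.82 in CS416144.1 and -4.64 in Gma#S4943143. Between the days it changed in 3646 probes in resistant leaves, by 4.30 in Gma#S45560842, 3.83 in Gma#S21540622, -5.75 in Gma#S45571233 and -5.45 in AX392312.1, the last a bound because Cy5 was saturated on all 3 arrays of day 1. In susceptible leaves it changed in 1147 probes, by 4.92 in Gma#S42153809, 4.52 in DJ381531.1, -4.61 in Gma#S45552984 and -4.105 in Gma#S45549946. The first pair shares part of its probe sequence and may measure 1 transcript. The interaction was called in 4 probes, at 3.30 in Gma#S46606366 (not exact, since Cy5 was saturated on all 3 susceptible arrays of day 10), -2.84 in Gma#S45563973, -2.65 in Gma#S39312610 and -2.44 in Gma#S45540140.

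Splits of 6 samples into 3 and 3 number 10, too few for a share under 0.05, and in each of the 6 comparisons 1 of the 10, the real split, reached the real count. The real split and the highest other gave 587 and 0 probes for the difference at day 1, 1170 and 0 at day 10, 4 and 0 for the interaction and 1602 and 0 for the Cy3 comparison. They gave 3646 and 1 for the change in resistant leaves and 1147 and 248 for the change in susceptible leaves. Of the splits that part every pair of days, 4 in number, the highest other gave 0 in both. The split with 248 calls kept both arrays of S51 together. Any split that does not part every pair keeps both arrays of more than 1 line together, so S51 is not singled out.

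The day 1 array of S51 stood apart from S50 and S52. Its slide is argued against, since its ratios correlated with S52 on that slide at 0.115 across probes and S50 correlated with S52 on another slide at 0.783. Non-inoculated leaves in its Cy5 channel could account for the median of -0.154 over 79 probes that rose at least 8-fold in resistant leaves at day 10, where S50 had 2.90 and S52 3.46. They could not give the median of 2.31 over 191 probes at least 8-fold up on the day 10 arrays of S50 and S52. The ratios of this S51 array correlated with the resistant arrays of day 1 at 0.31 to 0.36 across probes. These values lay above those with S50 (0.23) and S52 (0.12) of day 1. With the day 10 array of S50 the value was 0.31. Over the 70 probes that separate the lines, the Cy5 channel of this array lay on the susceptible side. A partial or different response of S51 stays open and was not tested.

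The Cy3 channels of a line lay close together on both days. In 0.277% of probes they differed at least 2-fold between days on average over the lines, but in 0.981% to 2.31% within single lines, against 4.30% to 10.4% between lines of 1 group. In resistant lines 471 probes were called between the days, against 0 in susceptible lines and 0 over all 6 lines. In Cy3, CS560318.1 in R46 went from 11.62 to 14.39. A shared extract per line used on both days and a low change of non-inoculated leaves over 9 days (median difference 0.0875) cannot be told apart, since no extract was hybridised again to set the scale. If an extract was used on both days, the ratios of day 10 could include leaf age.

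A total of 967 probes moved the same way in all 4 groups, which share 1 dye orientation. Of 251 other probes of the same GenBank entries, 98.4% had the same sign. That argues against a dye effect tied to the probe sequence only where the sequences of an entry differ. Whether they were identical or overlapped was not checked. A dye effect tied to the labelling of the transcript cannot be told apart from a shared response, since 17.2% of the probes differed between groups and no array had the dyes swapped.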

How the results depend on the processing

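Slide as a fixed block for the interaction and the Cy3 comparison, and the removal of saturated probes, were chosen after the data were seen. Of 155 alternative counts, 78 lay within 1.5 times the reported count and 77 further apart. Of 40 results of 34 named probes, 0 reversed under any setting run. The rule chose these probes for large changes with 1 sign or no overlap, so reversals were unlikely from the start. Of the 607 values of these results over all settings 491 stayed past the threshold and 116 did not, 78 of the latter with an array left out. With slide as a random block the counts were 15255 and 15891 for resistant leaves at day 1 and day 10. They were 10817 and 3183 for the changes in resistant and susceptible leaves, 46 for the interaction and 11609 in Cy3. An estimated slide correlation of -0.187 narrows the error of a mean over arrays of 1 slide, which raises the counts of resistant leaves by construction. It widens differences between arrays of 1 slide, so it does not account for every one of these counts. With slide as a fixed block limma called 0 probes at day 1, 0 at day 10 and 0 in the interaction (3476, 2887 and 1044 at an unadjusted p under 0.05) and 36 in Cy3, a fit that rests on S50. With line as a block (replicate block) the counts were 5543 and 2208 for the changes and 66 for the interaction. In Cy3 the count was 5341, with 12 arrays of 6 lines entered singly. With the compared groups alone they were 95 for susceptible leaves at day 1, 71 and 321 for the differences at day 1 and day 10 and 45 for the change in susceptible leaves. With array weights they were 12224, 3394, 3195 and 2330 for these results and 35 for the interaction. Scale normalisation gave 1235 and 628 for the differences, 477 for the change in susceptible leaves and 20 for the interaction. The interaction was 0 with median centring (2728 at an unadjusted p under 0.05), 7 with the strict filter and 10 with the authors' table. The Cy3 count was 929 and 866 on single days. With 1 array or line left out the ranges were 1791 to 3787 and 1753 to 8263 for resistant and susceptible leaves at day 1, 4612 to 5248 and 7509 to 9408 at day 10, 15 to 3079 and 416 to 1060 for the differences, 981 to 2631 and 150 to 971 for the changes, 0 to 4 for the interaction and 163 to 1931 in Cy3. Apart from the settings explained above, the cause was not tested. Without saturated probes the differences gave 435 and 944. The alternatives for gene lists were not run, since the probes have no descriptions. Low signal limits the probes below background and saturation limits the brightest.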

Other observations

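The test of the order of change was set before its result was seen; the medians without S51 and over risen probes were chosen after.

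In the inoculated channel alone, resistant and susceptible leaves differed in 144 probes at day 1, 65 higher and 79 lower in resistant leaves, and 101 of these also differed without inoculation. At day 10 they differed in 749 probes, 227 higher and 522 lower, and 541 of these were not called without inoculation. The same test in Cy3 called 929 probes at day 1 and 866 at day 10, of which 82 and 94 were outside the averaged baseline list. The Cy5 counts therefore do not measure a difference brought by inoculation, and a probe not called may still differ.

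A hypothesis is that susceptible leaves were ahead of resistant leaves in lowering transcripts at day 1. Over the 283 probes that fell at least 4-fold in resistant leaves at day 10, the median log2 ratio at day 1 was -1.03 in susceptible and -0.41 in resistant leaves. The difference of -0.61 (-0.614) goes with the hypothesis, and it was -0.82 without S51. The probes were chosen in resistant leaves alone and no set chosen in susceptible leaves was run. An earlier fall therefore cannot be told apart from a stronger one. At day 1 the medians were -1.16, -0.74 and -1.33 on the susceptible arrays and -0.53, -0.45 and -0.13 on the resistant ones. With 3 against 3 arrays an exact two-sided permutation test cannot go below 0.1. At day 10 they were -1.86, -2.20 and -1.97 on the susceptible arrays. The resistant ones had -2.75, -2.42 and -2.07, but the probes were chosen by these values, so the day 10 medians do not decide. Across tested probes susceptible day 1 correlated with resistant day 10 at 0.528, and resistant day 1 with susceptible day 10 at -0.0161. These correlations cover rises and falls and were not part of the planned test. Over the 79 probes that rose at least 8-fold in resistant leaves at day 10 the order rested on S51. The median at day 1 was 2.08 in susceptible and 2.49 in resistant leaves, and 3.18 in susceptible leaves without S51. The medians were 2.90, -0.15 and 3.46 on the susceptible arrays and 1.73, 2.64 and 3.03 on the resistant ones, so these probes do not decide the order.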
